A study of Calotropis procera with 8 samples.

How the data were processed

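Seedlings of *Calotropis procera*, a latex-bearing shrub of the dogbane family, were grown in a greenhouse for 3 months, pricked with a sterile needle and harvested whole at 1, 3 or 6 h, per the labels' protocols. Control seedlings formed a separate group, whose hour of harvest the labels do not give. Total RNA was copied from an oligo-dT primer, amplified as cRNA with the dye Cy3 and hybridised in 1 colour to a custom Agilent array, per the labels' protocols. Each of the 4 groups had 2 arrays. Groups were taken from the sample characteristics, and replicates from the sample titles. The titles carry letter codes for the replicates (BM or WBM and CM or WCM) that the labels do not explain, and here the first is called replicate 1 and the second replicate 2. Nothing in the labels says that replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

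The deposited scanner files hold intensity values, the brightness of each spot, read with Agilent Feature Extraction version 11.5.1.1, per the file headers. The program is also named in the submitters' processing notes. The processed intensity used here was already corrected for background and for trends across the array, per the file headers, and was not scaled between arrays. The files also hold the raw mean and local background intensities and the flags of each spot, other measures as deposited. A deposited table of the whole series holds log2 values for the same spots. Set against the scanner files, each of its columns equalled log2 of the processed intensity minus the array's 75th percentile, up to an offset of 0.000511 to 0.0021, so its scale and centring are known and it was used only as an alternative. The medians of its columns were -1.79 and -1.92 for control, -1.90 and -2.20 for 1 h, -1.88 and -2.04 for 3 h, and -1.87 and -1.97 for 6 h. No column of that table was left unused.

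The array carried 59412 transcript spots and 1319 control spots. The transcript spots held 27618 distinct sequences of 60 bases, of which 25034 were on 2 or more spots. Probe names refer to 13103 assembled loci and 28439 transcript models, with S or AS and other codes that the sources used here do not explain. Every probe description read Unknown and every gene name repeated the probe name, and no annotation table was given. Genes are therefore not named. The gene lists fixed before the data were examined, among them cell type markers, match on annotation text and could not be tested. In their place, 37 short peptide motifs were sought in the 3 forward reading frames of the probe sequences. They were chosen after the missing annotation was found and before any difference between groups was examined.

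For the main values, log2 of the processed intensity was taken, each array's 75th percentile over the transcript spots was subtracted, spots with an outlier flag were left out, and spots of one sequence were averaged. A sequence was tested if it was well above background on both arrays of at least 1 group, counting it so where at least 0.5 of its spots were flagged so. This left 25128 sequences (91.0%) from 12687 loci. Control spots were left out. No transcript spot was saturated. The tests were limma's lmFit and eBayes, two-sided, with all 8 arrays in 1 fit that share 1 estimate of the spread, which has 4 residual and 3.04 prior degrees of freedom. The p-values were adjusted by Benjamini-Hochberg over all sequences of a contrast, with a threshold of 0.05. The contrasts were 1, 3 and 6 h against control, 1 h to 3 h, and 3 h to 6 h, with a moderated F-test over the 3 contrasts against control. Motif groups with at least 5 tested sequences were compared with all other sequences by limma's camera at a preset correlation of 0.01, and again with an estimated correlation.

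Sequences are named by a rule fixed before the data were examined, which was written for probes with 1 per annotation. The distinct sequence as unit and 1 per locus took their place later. Without annotation the rule allows, for each time, at most 2 that rose and 2 that fell, taken by size of change. Each had to pass the test and be well above background on both arrays of the brighter group. Each also had to move the same way in all pairs of a wounded and a control array.

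The alternatives covered normexp background correction with an offset of 50, quantile normalization, median centring, the filter on dim spots, trend and robust variance estimates, a replicate block, the samples in the fit, the row of the slide, each replicate left out, the deposited table, the unit counted and a 2-fold minimum. Fits by probe name, with array weights and with 1 sequence per locus were added after the data were seen. All arrays came from 1 slide scanned on 1 day, per the file headers. Row 1 of the slide held the control and 1 h arrays and row 2 the 3 h and 6 h arrays. The 1 h contrast and the step from 3 h to 6 h thus lie within a row, where a term for the row changes nothing in the fit, and the other contrasts cannot be told apart from the row.

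The fit was tested on simulated data for the 1 h contrast, over 25128 sequences with 200 changed. The means were those of the control arrays and the spreads those estimated by eBayes. Noise was normal and independent between sequences, unlike overlapping probes of a locus. Of 50 sequences changed by each size, the fit recovered 0.0% at a log2 change of 1, 10.0% at 2, 86.0% at 4 and 96.0% at 6. There were 9 false calls at 1 h and 4 from 1 h to 3 h. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.445. Fits were run in R 4.3.3 with limma 3.58.1, and tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.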

Results

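Transcript levels were measured in whole 3-month-old seedlings of *Calotropis procera*, with 2 arrays of control seedlings and 2 each at 1, 3 and 6 h after the plants were pricked with a needle. The series title gives the purpose as the study of wound signalling in this plant. Between 87.2% and 91.0% of the transcript spots of an array were well above background. The 75th percentile of processed intensity was 1996 and 1611 for the control replicates, 1959 and 1182 at 1 h, 2169 and 1309 at 3 h, and 2034 and 1717 at 6 h. The median SD between 2 spots of one sequence was 0.047 to 0.080 on the log2 scale. Across sequences, which are not independent replicates, the correlation of log2 values was 0.941 to 0.965 between arrays of one group and 0.878 to 0.964 between arrays of different groups.

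The first principal component held 30.9% of the variance and placed 1 h replicate 2 at 147.5 and 1 h replicate 1 at 50.5, with the remaining arrays from -67.8 to -16.8. The second held 23.0% and ran from -86.2 and -54.3 for the control arrays to 45.1 and 102.0 for the 3 h arrays, with the 6 h arrays at 30.8 and -12.2.

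**Figure D1:**
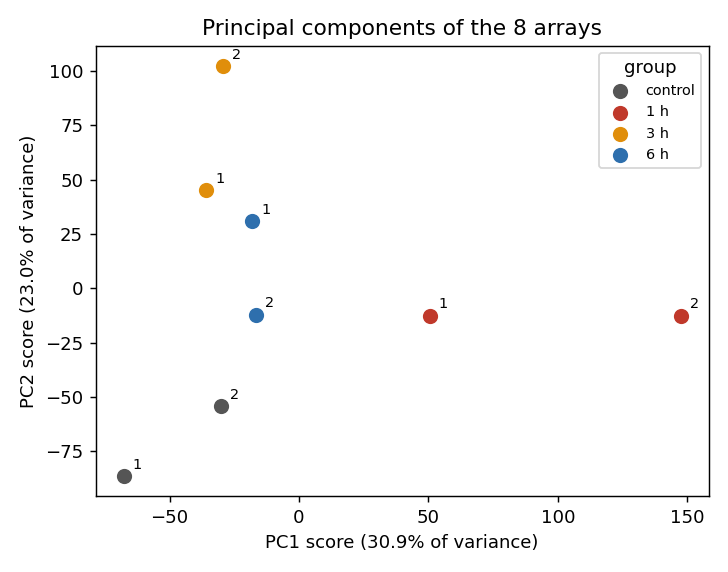
Scores of the 8 arrays on the first (x axis, 30.9% of variance) and second (y axis, 23.0%) principal components of the log2 values of 25128 sequences, without units. Each point is 1 array, coloured by group and marked with its replicate number, and the 1 h arrays lie at 50.5 and 147.5 on the x axis.

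The 1 h arrays were set against the control arrays to find transcripts that differ early after pricking. At 1 h, 335 sequences from 254 loci rose and 274 sequences from 185 loci fell, 609 of the 25128 tested. The risers had a median log2 fold change of 3.10, or 8.55-fold, and the fallers one of -2.92. The smallest change that passed was 1.56 in size on the log2 scale, against a median standard error of 0.445. Of the risers, 28 were not well above background on either control array, and 16 fallers were not so on either 1 h array, so that these have only a bound on the dim side. Among 105 loci with 2 or more called sequences, all 105 had calls of one direction. The uncalled sequences of loci with a call had that direction in 78.0% of 492 cases, against 49.8% for random uncalled sequences. Some probes of one locus overlap in most of their bases, and all are read on the same arrays. The agreement within loci is therefore not independent evidence of a response to pricking. The median of all sequences stood at -0.11 at 1 h, and centring the arrays on their median instead gave 393 rises and 200 falls. The count did not hold without some arrays, in fits where 1 group keeps 1 array and is measured less precisely. Without control replicate 1, without control replicate 2 or without 1 h replicate 2, limma kept no call. It called 721 without 1 h replicate 1, 388 without either 3 h array and 325 without either 6 h array. The 4 arrays of the control and 1 h groups, which fill 1 row of the slide, gave 33 calls when fitted alone.

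Among the sequences that rose at 1 h, probe GT_AS_Locus_8129_Transcript_1/1_1 had the largest change, with a log2 fold change of 7.43 (standard error 1.13, limma adjusted p = 0.0286). Its scaled log2 level was -5.95 ± 1.16 in control and 1.48 ± 2.23 at 1 h (SD, n = 2 each), and the difference from control was 4.02 at 3 h and 2.25 at 6 h, where it did not pass. Its sequence is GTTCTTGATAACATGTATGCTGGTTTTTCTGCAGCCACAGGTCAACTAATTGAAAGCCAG. The second, GT_S_Locus_4964_Transcript_9/11, differed by 7.22 (standard error 0.825, limma adjusted p = 0.0147) and was well above background on 1 of the control arrays. The other 10 tested sequences of its locus had the same sign with a median of 0.75, and 0 of them passed at 1 h.

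Among the sequences that fell at 1 h, GT_AS_Locus_426_Transcript_8/9_1 changed by -7.43 (standard error 0.842, limma adjusted p = 0.0145). Its level was 0.80 ± 0.09 in control, -6.63 ± 1.48 at 1 h and 0.90 ± 0.75 at 3 h (SD, n = 2 each), and the rise from 1 h to 3 h of 7.53 passed its own test (limma adjusted p = 0.0431). It was well above background on 1 of the 1 h arrays, and both other tested sequences of its locus had the same sign. Its sequence is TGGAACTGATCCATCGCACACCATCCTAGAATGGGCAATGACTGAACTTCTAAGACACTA. GT_S_Locus_18965_Transcript_1/1_1 changed by -6.88 at 1 h (standard error 0.679, limma adjusted p = 0.00953). The differences from control at 3 h and 6 h were -5.39 and -6.31 and did not pass (limma adjusted p = 0.077 and 0.150). Its sequence is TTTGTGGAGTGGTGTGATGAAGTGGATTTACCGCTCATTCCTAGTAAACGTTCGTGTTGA. Leaving out a control array or 1 h replicate 2 took the adjusted p of each of these 4 sequences over the threshold, in fits with 1 array fewer. The log2 changes were then 5.85 to 8.25 for locus 8129, 6.72 to 7.72 for locus 4964, -7.49 to -6.38 for locus 426 and -7.43 to -6.33 for locus 18965. The locus 8129 sequence also lost its call without either 6 h array (limma adjusted p = 0.0528). With the control and 1 h arrays alone, the locus 8129 and locus 426 sequences did not pass (limma adjusted p = 0.0874 and 0.0528), with changes of 7.43 and -7.43 as in the fit of all arrays, since only the estimate of the spread differs. Normexp background correction gave smaller changes for all 4, of 5.83 for locus 8129, 4.17 for locus 4964, -5.10 for locus 426 and -5.41 for locus 18965, which passed.

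**Figure D2:**
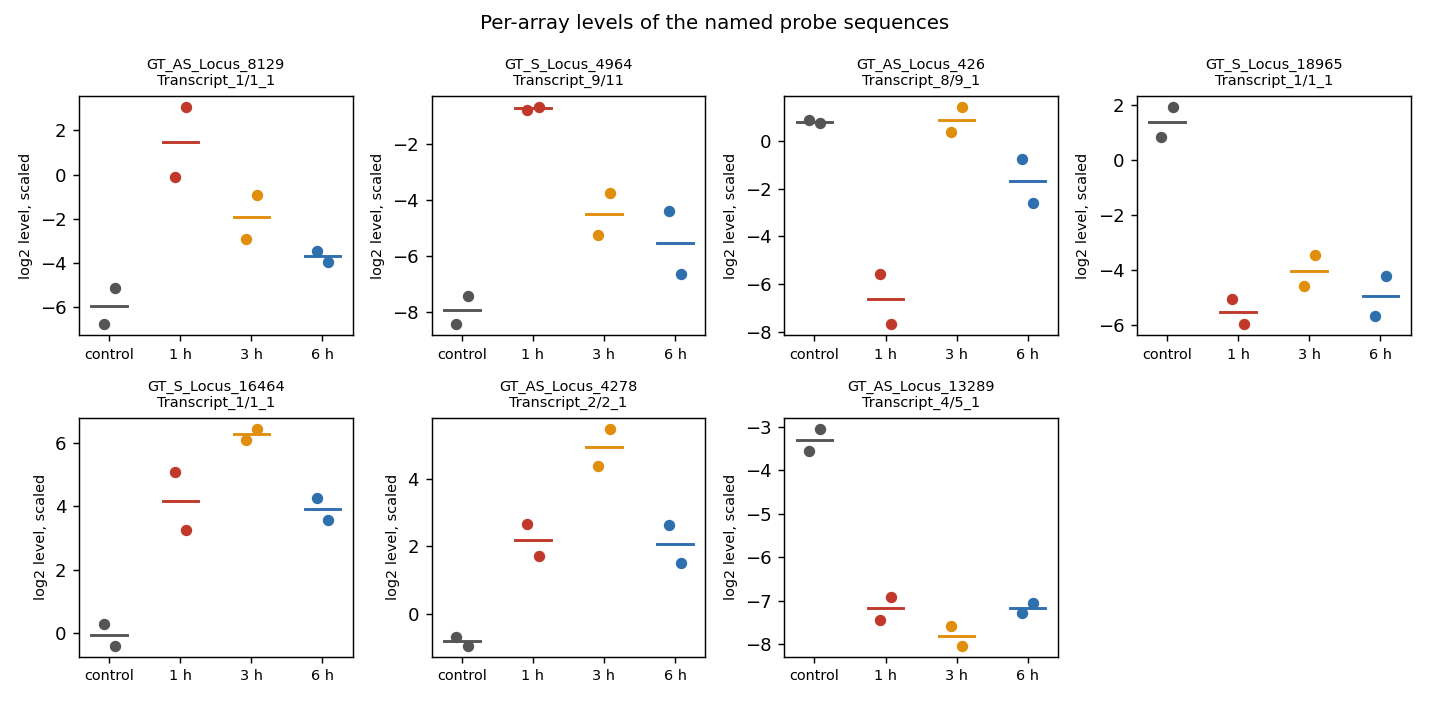
Scaled log2 level (y axis, log2 of processed intensity minus the array's 75th percentile) of the 7 named sequences in the control, 1 h, 3 h and 6 h groups (x axis). Each point is 1 array and each line the mean of a group's 2 arrays, and the level of the locus 426 sequence is -6.63 at 1 h and 0.90 at 3 h.

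At 3 h, 12 sequences differed from control: 9 rose, from 8 loci, and 3 fell, all from locus 13289. Among these 3, the probes of transcripts 3/5 and 4/5 overlap in most of their bases and are not separate measurements. The risers had a median change of 4.28 on the log2 scale. The sequence GT_S_Locus_16464_Transcript_1/1_1 had the largest rise, 6.32 (standard error 0.626, limma adjusted p = 0.0443), from -0.06 ± 0.49 in control to 6.26 ± 0.25 at 3 h (SD, n = 2 each). It had also risen at 1 h, by 4.22 (limma adjusted p = 0.026). GT_AS_Locus_4278_Transcript_2/2_1 rose by 5.76 at 3 h (standard error 0.571, limma adjusted p = 0.0443) and by 3.01 at 1 h (limma adjusted p = 0.0486). Their sequences are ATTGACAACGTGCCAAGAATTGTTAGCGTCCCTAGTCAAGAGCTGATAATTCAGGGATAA and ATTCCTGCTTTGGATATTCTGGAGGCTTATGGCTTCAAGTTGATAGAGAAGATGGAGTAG. Of locus 13289, GT_AS_Locus_13289_Transcript_4/5_1 changed by -4.50 at 3 h (standard error 0.369, limma adjusted p = 0.0365) and by -3.87 at 1 h (limma adjusted p = 0.00931). The difference at 6 h was -3.86, with limma adjusted p = 0.150. It was well above background on 1 of the 3 h arrays, and normexp correction gave a change of -1.79 that did not pass (limma adjusted p = 0.0656). Of the 7 other tested sequences of this locus, 4 had the same sign at 3 h and 2 of them passed. The call of the locus 16464 sequence was lost in 12 of 21 alternative fits, among them quantile normalization (change 6.34, limma adjusted p = 0.0561), with changes of 5.97 to 6.67 over all of them. That of the locus 4278 sequence was lost in 11 of 21, with changes of 5.20 to 6.31. The named locus 13289 sequence lost its call in 11 of 18, with changes of -4.76 to -1.79. Not all of these fits are separate, since leaving out either 1 h array gives the same result, as does either 6 h array. Leaving out any 1 of the 8 arrays left 0 calls at 3 h. The 3 h and control arrays lie in different rows of the slide, so the contrast cannot be told apart from the row.

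At 6 h, limma called 0 sequences against control. The smallest adjusted p was 0.150, and 2078 sequences had an unadjusted p under 0.05, where 1256.4 were expected by chance. This contrast too is confounded with the row of the slide. In the moderated F-test over the 3 times, 95 sequences differed, of which 84 were also called at 1 h and 12 at 3 h. That count was 0 without any 1 of the 8 arrays.

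The steps set one wounded group against another, and the control arrays enter them only through the shared estimate of the spread. From 1 h to 3 h, 79 sequences rose and 49 fell, 128 in all, again between different rows of the slide. Of the 335 risers at 1 h, 39 fell in this step. Of the 274 fallers, 49 rose in it. Both contrasts hold the 1 h arrays with opposite signs, so such turns arise without any change: with as many sequences taken per contrast, 20 simulations of unchanged groups gave 37 to 56 of them, with a mean of 47, against the 88 observed. The simulation leaves out real effects, so the excess is not a count of transcripts that returned. The medians of the risers were 3.10, 1.32 and 0.82 at 1, 3 and 6 h, and those of the fallers -2.92, -0.91 and -1.44. Choosing the sequences at 1 h enlarges the first value, and the shared control arrays pull the later ones toward the same sign. Leaving out 1 h replicate 2 or any 3 h or 6 h array left 0 calls in the step, leaving out a control array left 8, and leaving out 1 h replicate 1 gave 185. From 3 h to 6 h, limma called 0 sequences, with 2133 at an unadjusted p under 0.05 and a smallest adjusted p of 0.332.

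**Figure D3:**
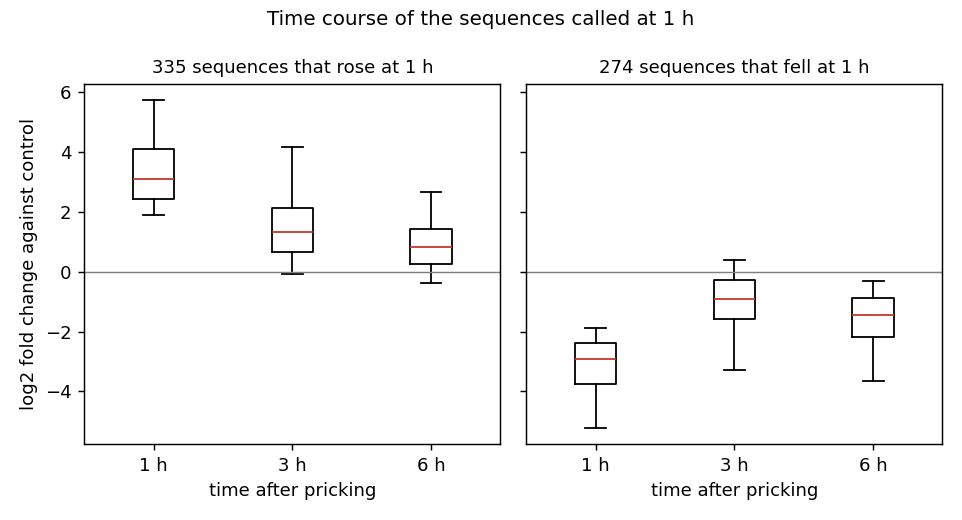
Log2 fold change against control (y axis) at 1, 3 and 6 h (x axis) of the 335 sequences that rose at 1 h (left) and the 274 that fell (right). Boxes span the quartiles with the median as a line, whiskers run from the 5th to the 95th percentile, and the medians go from 3.10 to 0.82 on the left and from -2.92 to -1.44 on the right.

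The times were also compared with one another. Of the 12 sequences called at 3 h, 7 were called at 1 h, all in the same direction, where independent lists would share 0.153 in one direction. Unchanged groups simulated against the same control arrays, with as many sequences taken at each time, shared 7.95 in one direction on average and at most 11 over 20 simulations. The overlap did not exceed that of the simulated unchanged groups. The simulation leaves out real effects, so the overlap alone cannot tell whether the same transcripts changed at both times. Across sequences, the correlation of log2 fold changes was 0.469 between 1 h and 3 h, 0.508 between 1 h and 6 h, and 0.660 between 3 h and 6 h. Unchanged groups simulated against the same controls gave 0.497, 0.499 and 0.496. The covariance was 0.457, 0.421 and 0.493, against simulated values of 0.156, 0.157 and 0.156. With each time set against a different control array, a comparison added after the data were seen, the covariance was 0.266 to 0.286 between 1 h and 3 h, 0.209 to 0.273 between 1 h and 6 h, and 0.291 to 0.335 between 3 h and 6 h. The correlations were then 0.233 to 0.249, 0.206 to 0.272 and 0.312 to 0.366. The 3 h and 6 h arrays share a row of the slide, and both control arrays lie in the other. A difference between rows would enter both contrasts alike, and splitting the controls does not remove it. The higher values between 3 h and 6 h therefore cannot be told apart from the row.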

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

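The quantile and slide row fits were planned, but their use as tests of an explanation was chosen after the counts had been seen, as were the intensity of 100 that defines a bright spike-in sequence and the interval and the count of distinct pairs used for the strand pairs. The 609 calls at 1 h vanish without 1 h replicate 2 or either control array, and 1 h replicate 2 stands farthest out on the first principal component. If that array alone made the pattern, sequences chosen from it would not keep their sign in other arrays. Of the 500 sequences with the largest change between 1 h replicate 2 and control replicate 2, 93.4% had the same sign between 1 h replicate 1 and control replicate 1. That share argues against a single aberrant array as the source of those directions. With the control arrays crossed, 500 sequences were chosen anew by their change between 1 h replicate 2 and control replicate 1. Of these, a smaller share, 78.6%, had the same sign between 1 h replicate 1 and control replicate 2. Quantile normalization, which gives all arrays one brightness distribution, left 627 calls, which argues against that distribution as the whole cause. The control and 1 h arrays lie in 1 row of the slide, so a difference between rows is no part of this contrast, and the 33 calls of those arrays fitted alone do not bear on it. Within the row each group holds its own columns, so column and group cannot be told apart. A response to pricking remains a candidate explanation, and the hour of harvest of the control plants, which the labels do not give, stays open and untested.

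The 128 sequences that differ between 1 h and 3 h stand out because the test of the difference between the effects at those times passed. Among the named sequences, GT_AS_Locus_426_Transcript_8/9_1 did so, with a difference of 7.53 on the log2 scale (limma adjusted p = 0.0431). It was well above background on only 1 of the 1 h arrays. The 1 h and 3 h arrays lie in different rows of the slide. Sequences chosen for a large change at 1 h tend to turn in this step, which holds the same 1 h arrays.

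Control spots, which no comparison uses, gave a signal on 1 array above that of the controls. The brightest E1A spike-in sequence, from an adenovirus transcript added for labelling checks, had an intensity of 147530 on 1 h replicate 2. It was 1843 and 11830 on the control arrays, 3261 on 1 h replicate 1, 3010 and 8330 on the 3 h arrays, and 1494 and 4674 on the 6 h arrays. Over 7 spike-in sequences brighter than 100 on 1 h replicate 2, the log2 ratio to the mean of the other arrays was 5.36 with an SD of 0.33, and over the 3 that were brighter than 100 on every array the SD was 0.18. A nearly constant ratio is consistent with the same mix being present in traces on the other arrays. Whether it was added to that sample alone is not given in the sources used here.

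On the array, 2505 pairs of probes are reverse complements of each other, and for 868 pairs both strands were well above background on all arrays, against 1381 with exactly 1. In 76 pairs with both probes tested and at least 1 called at 1 h, both had the same sign in 73.7% (Wilson 95% interval 62.8 to 82.3). The prediction set in advance counted called probes with a partner well above background, while here the partner had only to pass the filter for testing. Per called probe, the partner had the same sign in 75.6% of 82 cases. This meets the bound of 75 but enters 6 pairs as 12 cases. Both were called in 6 pairs, in the same direction each time. The interval spans that bound, set in advance for a double-stranded signal read by both probes, so that reading and transcripts from both strands cannot be told apart here.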

How the results depend on the processing

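Fits by probe name, with array weights and with 1 sequence per locus were chosen after the data were seen. The counts at 6 h and from 3 h to 6 h were 0 in every fit run. At 1 h the count stayed within 1.5 times of 609 under normexp (851), quantile normalization (627) and median centring (593). So it did under both dim filters, trend and robust estimates, 1 probe per transcript and 1 sequence per locus (422 of 12687 tested). The deposited table and a 2-fold minimum gave the same 609, an outcome fixed by their setup. The table differs only by a small offset per array, and the smallest called change was 1.56 on the log2 scale. The count was 278 with array weights and 1272 by probe name, which counts repeated spots. It was 33 with the 2 groups alone, which at 1 h is the same fit as the arrays of 1 row, where fewer samples estimate the spread. At 3 h, against 12, normexp gave 159, trend and robust estimates 59, probe names 37, 1 sequence per locus 4, and the 2 groups alone 0. For the F-test, against 95, normexp gave 629, trend and robust estimates 358, probe names 246, median centring 143 and array weights 41. From 1 h to 3 h, against 128, normexp gave 594, trend and robust estimates 449, probe names 322, the filter on all 8 arrays 217, no filter 29, array weights 1 and the 2 groups alone 0. Apart from the counts by probe name and in fewer samples, the cause was not tested.

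Leaving out 1 array gave 0 to 721 calls at 1 h, 0 to 0 at 3 h and in the F-test, and 0 to 185 from 1 h to 3 h, with the lone array of a group assumed to vary like the other groups. The title codes as a replicate block gave 423 calls at 1 h, 0 at 3 h, 0 in the F-test and 4 from 1 h to 3 h. The labels do not say that the codes pair samples, and the data do not settle it. Correlations of the within-group differences ran from -0.17 to 0.36, not all over 0.1, with the largest between control and 1 h. Replicate 2 was dimmer in all 4 groups, while its brightest E1A spike-in sequence was brighter in each. Over the 7 named sequences, the alternatives gave 144 pairs of a sequence and a fit, with the direction kept in all and the call in 92. Some of these fits repeat one another. Leaving out either array of a group outside the contrast gives the same result, as do the 2 groups alone and the arrays of 1 row at 1 h. The 144 are therefore not all separate alternatives. The naming rule required 1 direction in all pairs of a wounded and a control array. Leaving out an array could therefore not reverse it, and the kept direction is no independent check. The gene lists and their camera alternative were not run, since the probes carry no annotation, and contrasts between rows of the slide have no within-row value. Signal near background limits the 28 rises and 16 falls at 1 h with a dim side below it.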

Other observations

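The bootstrap intervals, the splits of the arrays and the test over probe name codes were chosen after the data were seen. With no annotation, motifs in the probe sequences were the way to gene groups, and 4 of the 37 motif groups had at least 5 tested sequences. None passed limma's camera after adjustment at any time. A motif match does not establish what a transcript encodes. Over all probe sequences, the other strand gave 1 EF-hand match against 5 as printed, and 1 TIFY or Jas match against 9. It gave 4 histone matches against 13 and 0 ubiquitin matches against 10. Of 5 sequences that match an EF-hand loop, the calcium-binding motif of calmodulin-like proteins, 2 were called at 1 h. Chosen after their values were seen, these are GT_S_Locus_14038_Transcript_1/1_1, which rose by 4.83 (standard error 0.886, limma adjusted p = 0.045), and GT_S_Locus_18344_Transcript_1/1_1, with a change of -2.37 (standard error 0.421, limma adjusted p = 0.0429). The 8 sequences with a TIFY or Jas motif, found in the repressors of jasmonate signalling, ranged from -0.96 to 2.90 at 1 h around a median of 0.30, and 0 passed there (camera adjusted p = 0.354, and 0.511 with an estimated correlation). Their medians were -0.39 at 3 h and -0.19 at 6 h.

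Histone H3 and H4 motifs were read in 12 tested sequences. The hypothesis that these transcripts shift together was left undecided: the medians were 0.08, -0.17 and -0.32 at 1, 3 and 6 h, and the smallest unadjusted camera p was 0.038 at 6 h (adjusted p = 0.152, and adjusted p = 0.670 with an estimated correlation), with 9 of 12 below 0. Ubiquitin motifs were read in 10 sequences. A joint rise was not shown either: the medians were 0.25, 0.18 and -0.10 at 1, 3 and 6 h. The smallest unadjusted camera p was 0.0963 at 1 h (adjusted p = 0.354). The 95% bootstrap interval of the median at 1 h was 0.06 to 0.57. That interval describes the spread over the 10 sequences, which come from 7 loci and were read on the same arrays. It does not measure the spread between samples. The interval therefore neither shows a joint rise nor excludes one of the size set in advance, and the question was left undecided.

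Agreement between arrays at the later times was larger than the counts of calls show. With the 8 arrays split into disjoint sets of 1 wounded and 1 control array, the correlation of log2 fold changes across sequences was 0.585 at 1 h, 0.434 at 3 h and 0.328 at 6 h, and 0.291, 0.352 and 0.274 with the control arrays crossed. At 6 h, where limma called 0 sequences, the 500 with the largest change in one set had the same sign in the other in 77.2% to 81.8%. The row of the slide is shared by both sets at 3 h and 6 h.

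For the sequences called at 1 h, the values at 3 h and 6 h were also set against each other, without a test of the set. The 3 h and 6 h arrays entered the choice of these sequences through the shared estimate of the spread. Over the 4 pairs of a 3 h and a 6 h array, 69.7% to 77.0% of the 274 that fell at 1 h were lower at 6 h than at 3 h, with medians of -0.39 to -0.80. Of the 335 that rose at 1 h, 58.8% to 83.3% were lower, with medians of -0.13 to -0.98. The median of all sequences in those pairs lay between -0.07 and 0.01. No single one of the called sequences passed limma's test of that step. GT_Xhyb_AS_Locus_12771_Transcript_5/6_197162_1, chosen after its values were seen, was the one sequence that rose at 1 h and again from 1 h to 3 h, by 1.88 and 2.47 (limma adjusted p = 0.0496 and 0.0481).

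The share of calls at 1 h was compared over 7 classes of code in the probe names. Of 1603 tested sequences coded GT_Spec_S, 3.62% were called (two-sided Fisher's exact test, adjusted p = 0.0167), but sequences of one locus are not independent. With 1 sequence per locus, 3.41% of 792 were called and no class passed (adjusted p = 0.298 for GT_Spec_S, smallest adjusted p = 0.0779).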
